A study of Mus musculus with 12 samples.

How the data were processed

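Gene expression was measured in 12 samples of sorted premalignant pre-B cells of Eµ-Myc transgenic mice, 6 Smchd1 null and 6 Smchd1 wildtype, with 1 Illumina mouse BeadChip array per sample. Groups, replicate numbers and BeadChips were taken from the labels. Total RNA was extracted with a column kit, and biotin-labelled cRNA was prepared from it, per the labels' protocols. The deposited tables give mean bead intensity per probe on a linear scale as the scanner software exported it, with a detection score and a bead count per probe and a separate table of control probes, per the file headers. The detection score is a fraction equal to 1 minus the detection p-value of the deposited table, both made by the scanner software against the negative controls. A further deposited table holds the authors' processed log2 values. The submitters' processing notes name BeadStudio, limma 3.12.1 and R 2.15.1, and the file headers name GenomeStudio 1.8.0. No genome build is given in the sources used here.

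The deposited intensity values were background-corrected with the 936 negative control probes (normexp), quantile normalized together with an offset of 16 and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). These values differed from the authors' processed log2 values by at most 5.0e-09, so a run on the latter moves nothing. All log2 levels are of this scale. Levels of the probes of a gene were ranked only to choose or name its brighter probe. A probe was tested when its detection p was under 0.05 on at least 3 of the 12 arrays, which kept 17607 of 45281 probes (12062 symbols) and left out 27674 dim ones. Where a probe was detected on no array of a group, the fold is a bound, printed as at least N-fold. The same bound serves where a group's mean lay under the lowest detected signals of its arrays, a rule added after the data were seen. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal.

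Each probe was fitted with limma's lmFit and eBayes, null against wildtype with no covariate, and p-values were adjusted by Benjamini-Hochberg over all tested probes. All adjusted p-values of single genes come from this fit, and changes are null minus wildtype on the log2 scale. Probe names in the files are older symbols: 27400 probes matched a current symbol in the gene table for assembly GRCm38.p6, 8341 matched through a synonym and 9540 kept the file's name. That table served for names, chromosomes and neighbour order only. Immunoglobulin segment names are printed without the accession-like suffix the files give.

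The 29 gene lists and the rule for named genes were fixed before the data were examined. Named were Smchd1, then the 12 genes with the largest rise and the 12 with the largest fall among probes at adjusted p under 0.05, with 1 probe per gene. Symbols beginning with LOC, or with Gm or BC and a digit, blank ones and those ending in Rik were counted and not named (56 of the 215 changed probes). Up to 4 members of smallest p per list were also named, with Xist and the Y-linked genes. Igf2, H19, Cox7a2l, C030034I22Rik, Lbh, Yipf4, Spast and Ccnd1 fall outside the rule and were chosen after their values were seen. Lists with at least 3 tested genes, 27 in all, were tested with camera at a preset correlation of 0.01, 1 probe per gene, that of the highest mean. Adjusted over these lists, 14 passed (10 higher, 4 lower) and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. A further test, fry, which asks only whether a list's genes move one way, called 10. These included the protocadherin and other imprinted lists, which camera did not call. Called by camera but not by fry were the interferon (fry adjusted p = 0.11), myeloid (0.37), plasmacytoid dendritic (0.11), cell cycle (0.11), chromatin silencing (0.080) and pre-B receptor (0.11) lists.

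The fit was tested on simulated data with the means and spreads of the 17607 probes of the null against wildtype comparison and independent noise. Of 67 probes changed by 0.5 log2 40.3% were recovered, of 67 changed by 1 89.6%, and of 66 changed by 2 100%, with 11 calls among unchanged probes. On 12062 simulated genes 5 of 5 lists of 20 genes shifted by 0.5 were called and 0 of 45 others. This simulation holds no correlation between genes, which real lists have.

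Alternatives were other background corrections and normalizations, no filter or a stricter one, BeadChip or the replicate number as a block, each BeadChip alone, array weights, another prior, the X and Y lists left out, each array left out, 1 probe per gene, and other set tests. Further ones were added after seeing the data: null arrays with high levels of other cell types' genes left out, these levels as covariates, and probes on X or Y or near Smchd1 left out.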

Results

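The series profiled premalignant pre-B cells from Eµ-Myc transgenic mice, in which Myc is driven in B-lineage cells before lymphoma appears, on the C57BL/6 background. The 6 null samples were homozygous for a gene-trap allele of Smchd1, a chromosomal protein with an SMC hinge domain known for its part in X inactivation and in silencing clustered and imprinted genes, and the 6 wildtype samples carried no such allele. Per the labels the cells were taken directly from mice and isolated by cell sorting, and total RNA of each sample was hybridised to 1 Illumina mouse array of 45281 probes. The labels do not say whether each sample came from 1 mouse, so the p-values measure the spread between these samples. The number of probes detected per array ran from 15396 (wildtype 2) to 16587 (null 3). Mean raw intensity lay between 3.08 (null 4) and 4.43 (null 2) times the mean of the negative control probes, and the number of arrays limits the precision. Each of the 2 BeadChips held 3 null and 3 wildtype arrays, with null 4, 5 and 6 on BeadChip 1 and null 1, 2 and 3 on BeadChip 2.

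Smchd1 itself was reported first, as a check of the labels. Its brightest probe fell from a log2 intensity of 9.47 ± 0.14 in wildtype to 5.05 ± 0.35 in null arrays (SD, n = 6 each), a 21.4-fold lower level, and was still detected on 4 of the 6 null arrays. The log2 change was -4.42 (SE 0.14, limma adjusted p = 1.3e-09), with -4.54 on BeadChip 1, -4.30 on BeadChip 2 and -4.42 with BeadChip as a block. The second tested probe fell by 1.39 on the log2 scale and remained detected on all 6 null arrays. The third was detected on all 6 wildtype and 0 null arrays and was at least 1.87-fold lower. The remaining 2 Smchd1 probes were detected on no array, and where the trap lies relative to the probes is not given in the sources used here. Xist, the transcript that coats the inactive X in females, was detected on 0 of 12 arrays by any of its 4 probes, and 1 probe each of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was detected on all 12.

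The comparison asked which genes change in premalignant pre-B cells that lack Smchd1. In null cells 94 probes rose and 121 fell, together 215 of 17607 tested (limma, adjusted p under 0.05). By the fitted change 42 of the risers and 34 of the fallers changed at least 2-fold, but for 49 of the 215 the fold is only a bound. The largest fitted rise among named genes belonged to Ndn, an imprinted gene of the Prader-Willi region that encodes necdin. Ndn was detected on 0 wildtype and 6 null arrays (4.49 ± 0.05 against 8.88 ± 0.58), which made it at least 15.4-fold higher. Isl1, a LIM-homeodomain factor of motor neurons detected on 1 wildtype array, was at least 5.59-fold higher, and Elavl2, a neuronal RNA-binding protein detected on 0 wildtype arrays, was at least 3.96-fold higher. Reln, a secreted guidance protein, rose by 1.89 (SE 0.27), and Ncam1, a neural adhesion molecule detected on 0 wildtype arrays, was at least 2.32-fold higher. The heparan sulphate proteoglycan Gpc1 rose by 2.45 (SE 0.19) and was detected on every array. Eml1, a microtubule-binding protein detected on 2 wildtype arrays, was at least 3.74-fold higher. Lrig3, a membrane protein detected on 0 wildtype arrays, was at least 3.20-fold higher, the calcium-binding S100a6 rose by 1.94 (SE 0.35) and the metallothionein Mt1 by 1.82 (SE 0.27). For all 10 of these genes the 6 null arrays lay above the 6 wildtype arrays. Csprs, detected on 2 wildtype arrays, was at least 9.25-fold higher, with null levels from 6.00 (null 2) to 11.33 (null 5). Its fitted change of 3.41 was 2.79 without null 5, and its call was lost in 8 of 12 runs that left out 1 array, on BeadChip 1 (limma adjusted p = 0.17), on BeadChip 2 (0.36) and with null 3 and 5 left out (0.054). Leaving out 1 array also ended the call in 5 of 12 runs for Lrig3 and in 3 each for S100a6 and Ncam1. Over all settings run, the call was lost in 11 of 30 for Lrig3, 7 of 30 for S100a6 (lowest change 1.08) and 6 of 29 for Ncam1.

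**Figure D1:**
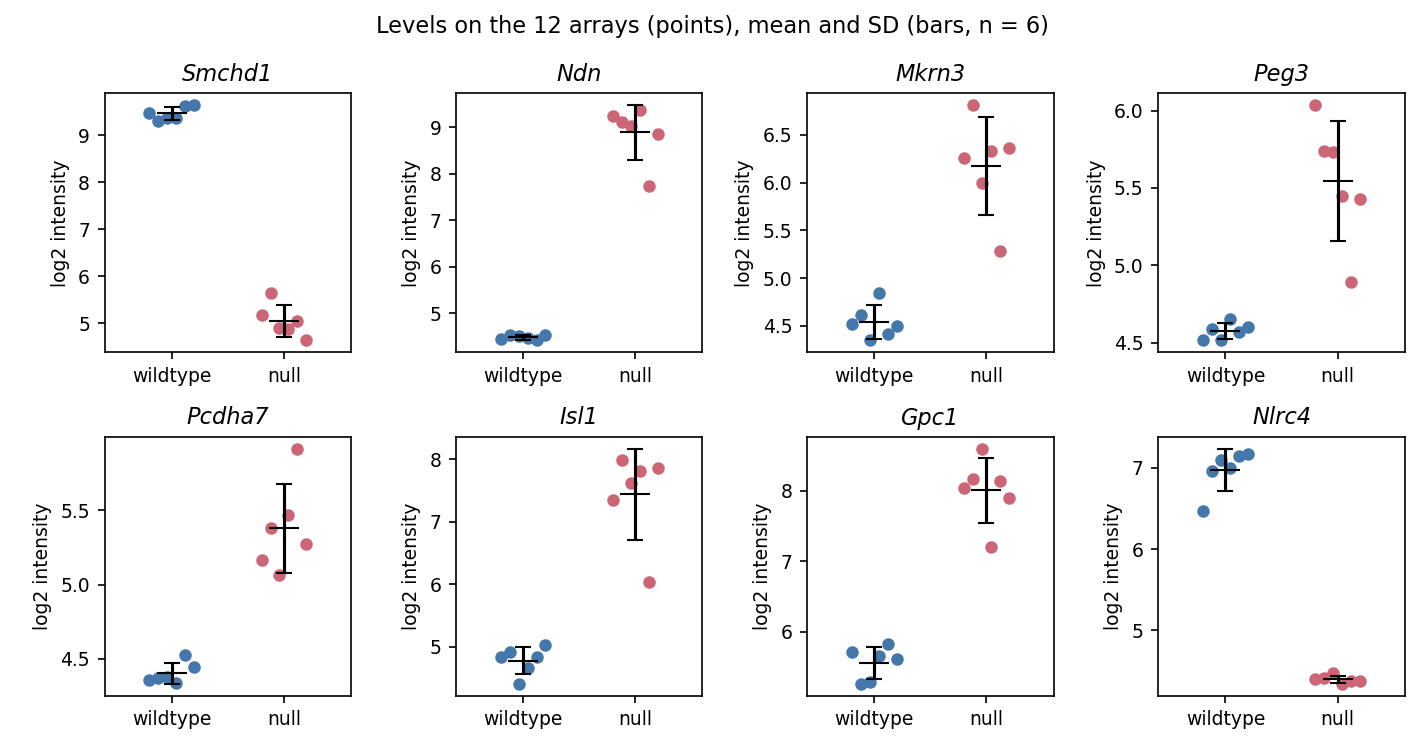
Log2 intensity (vertical axes) of 8 genes on each array, with wildtype arrays at the left and null arrays at the right of each panel; points are arrays and bars give the mean and SD (n = 6). Ndn stands at 4.49 in wildtype and 8.88 in null arrays, while Smchd1 stands at 9.47 and 5.05.

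After Smchd1, the largest fitted fall among named genes was that of Nlrc4, an inflammasome sensor, which was detected on all 6 wildtype and 0 null arrays. It was at least 4.12-fold lower in null cells, a bound that does not rank it above the 5.53-fold fall of IGH-VJ558. Immunoglobulin variable segments made up 5 of the 12 largest named falls. IGH-VJ558, a heavy-chain variable family, fell from 11.09 ± 0.78 to 8.62 ± 1.17, and IGK-V5, a kappa-chain family, fell from 8.99 ± 0.51 to 7.15 ± 0.87. IGHV1S59, IGHV1S119 and IGHV10S1 fell by 1.15, 1.11 and 1.06 on the log2 scale. Members of a variable segment family are similar in sequence, and which members a probe reads is uncertain. Epb41l4b, a band 4.1 family protein detected on 3 null arrays, was at least 2.22-fold lower. Mta3, a subunit of the NuRD complex, fell by 1.19 (SE 0.20), and its second called probe by 1.04. It lies 39 tested genes from Smchd1 on chromosome 17 and was lowest in null 1 (8.83) and null 2 (8.85), against 9.08 to 9.95 in the other null arrays. The transcriptional co-regulators Sertad4 and Lmo4 fell by 1.16 (SE 0.13) and 1.10 (SE 0.20), and the TNF receptor family member Tnfrsf19 by 1.08 (SE 0.20). Of 12 runs that left out 1 array, the call was lost in 8 for IGH-VJ558, 6 for IGK-V5, 9 each for IGHV1S59 and IGHV1S119, 5 for Tnfrsf19 and 3 each for IGHV10S1 and Lmo4. Over all 30 settings run, it was lost in 4 for Epb41l4b (limma adjusted p up to 0.34), 3 for Mta3 and 2 for Sertad4.

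**Figure D2:**
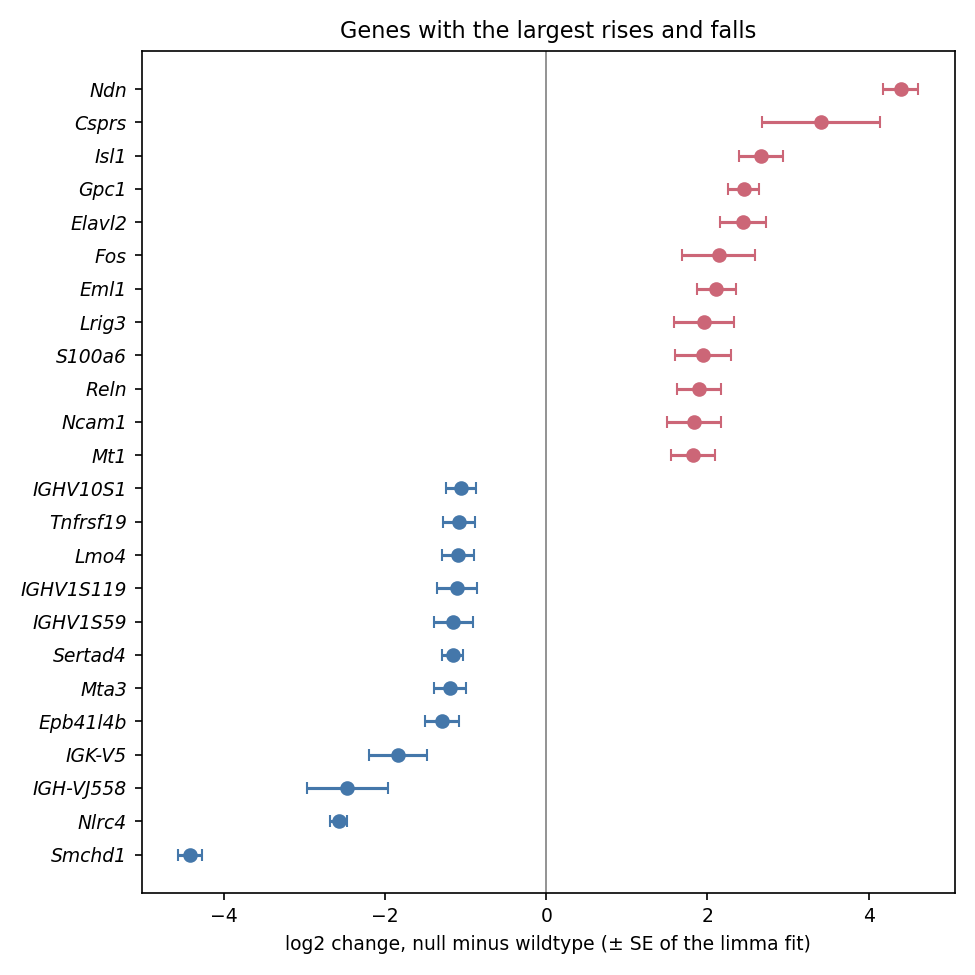
Log2 change, null minus wildtype (horizontal axis), of Smchd1 and the genes with the largest rises and falls (vertical axis), with the standard error of the limma fit; n = 6 arrays per group. Ndn marks the top at 4.40 and Smchd1 the bottom at -4.42; for genes at background in 1 group the plotted fit is no exact fold.

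With BeadChip as a block the counts were 128 higher and 176 lower, and within a BeadChip, 3 arrays against 3, they were 7 higher and 5 lower on BeadChip 1 and 33 higher and 10 lower on BeadChip 2. With median scaling in place of quantile normalization 59 probes were higher and 33 lower. The count fell by over 1.5 times without wildtype 1 (106), wildtype 2 (88), wildtype 3 (68), wildtype 4 (70), wildtype 6 (68) or null 3 (132).

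Genes of the classes tied to Smchd1 before, as fixed lists, were asked about as groups. Of 5 tested genes of the imprinted Snrpn cluster 2 rose and 0 fell, and the list was higher in null cells (camera adjusted p = 0.0033), with adjusted p = 0.19 with an estimated correlation. Beside Ndn, Mkrn3, a maternally imprinted RING-finger gene detected on 0 wildtype and 6 null arrays, was at least 2.36-fold higher (6.18 ± 0.51 against 4.54 ± 0.17). Ube3a (-0.17, limma adjusted p = 0.45) and Snurf (-0.08, limma adjusted p = 0.78) of the same cluster did not pass, and 2 genes passed when adjusted over the list alone. The list mean was higher by 1.18 on BeadChip 1 and 1.17 on BeadChip 2. Among 21 other imprinted genes 1 rose, Peg3, a paternally expressed zinc-finger gene detected on 0 wildtype and 5 null arrays and at least 1.53-fold higher; 2 passed when adjusted over the list alone, Cdkn1c, a cyclin-dependent kinase inhibitor, being at 1.05 (SE 0.25, limma adjusted p = 0.058). The list as a whole did not pass (camera adjusted p = 0.12), though fry called it higher (fry adjusted p = 0.036). The only tested member of the Igf2r cluster, Igf2r, was at 0.25 (SE 0.14, limma adjusted p = 0.35). Of 54 clustered protocadherins on the array, cell-surface genes chosen singly in neurons, only 4 were bright enough to be tested. Of these Pcdha7 rose: 2 of its probes were detected on 0 wildtype arrays, and the brighter was at least 1.36-fold higher. Pcdhgc5 (-0.14), Pcdhgb4 (0.09) and Pcdhb4 (0.02) did not pass and the list did not either (camera adjusted p = 0.12), with 1 gene passing when adjusted over the list alone. By fry the protocadherin list was called higher (fry adjusted p = 0.030). The 8 tested Hox genes (camera adjusted p = 0.36), 3 germline genes (0.64), 4 Y-linked genes (0.30) and 4 X-inactivation and escape genes (0.30) had 0 changed members, over all probes or adjusted over the list alone. The array held 39 Hox and 25 germline genes of these lists, so most of both were too dim to be tested.

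Genes that define the B lineage were lower in null cells as groups, though 0 of their members passed singly (limma; 3 and 9 had an unadjusted p under 0.05). The 13 tested genes of the pre-B cell receptor and V(D)J recombination list had a mean log2 change of -0.29 (camera adjusted p = 0.018; adjusted p = 0.39 with an estimated correlation), and 2 fell when adjusted over the list alone. Its largest change was that of Rag1, the recombinase subunit (-0.92, SE 0.28, limma adjusted p = 0.12), beside Syk, a receptor-proximal kinase (-0.41, SE 0.10, limma adjusted p = 0.068). The 20 early B-lineage genes had a mean of -0.22 (camera adjusted p = 0.030; adjusted p = 0.27 with an estimated correlation), 3 falling when adjusted over the list alone, with Il7r, the receptor for interleukin-7, at -0.99 (SE 0.28, limma adjusted p = 0.10) and the B-cell repressor Bach2 at -0.71 (SE 0.20, limma adjusted p = 0.091). On BeadChip 1 the 2 list means were -0.24 and -0.25 and neither list passed (camera adjusted p = 0.26 and 0.24), while on BeadChip 2 they were -0.33 and -0.19 and both passed. The pre-B receptor and early B lists stood at -0.87 and -0.57 in null 5, where the plasmacytoid dendritic mean was 2.60, the T and NK mean 1.42 and the plasma cell mean 1.32, while null 4 was at 0.41 for the pre-B receptor list. With null 3 and null 5 left out, the arrays with the highest myeloid and plasmacytoid dendritic means, the pre-B receptor list did not pass (mean -0.17, camera adjusted p = 0.14). It also did not without null 5 alone (-0.17, adjusted p = 0.063) or null 1 (-0.25, 0.059), nor did the early B list without null 1 (-0.23, 0.060) or null 2 (-0.23, 0.057). The early B list also did not pass with a stricter filter on dim probes (-0.23, 0.053). With the myeloid and plasmacytoid dendritic means as covariates neither list passed, at -0.12 for the pre-B receptor (adjusted p = 0.35) and -0.13 for the early B list (0.13). The 24 genes of later B-cell maturation did not pass (camera adjusted p = 0.70), with a mean of 0.05 and a median of -0.01. Immunoglobulin variable segments, a group chosen after its values were seen, were lower on all 44 tested probes, of which 13 fell; the mean change was -0.82 log2. Their mean fell short of the wildtype mean by most in null 5 (-1.29) and null 4 (-1.22) and by least in null 1 (-0.45).

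**Figure D3:**
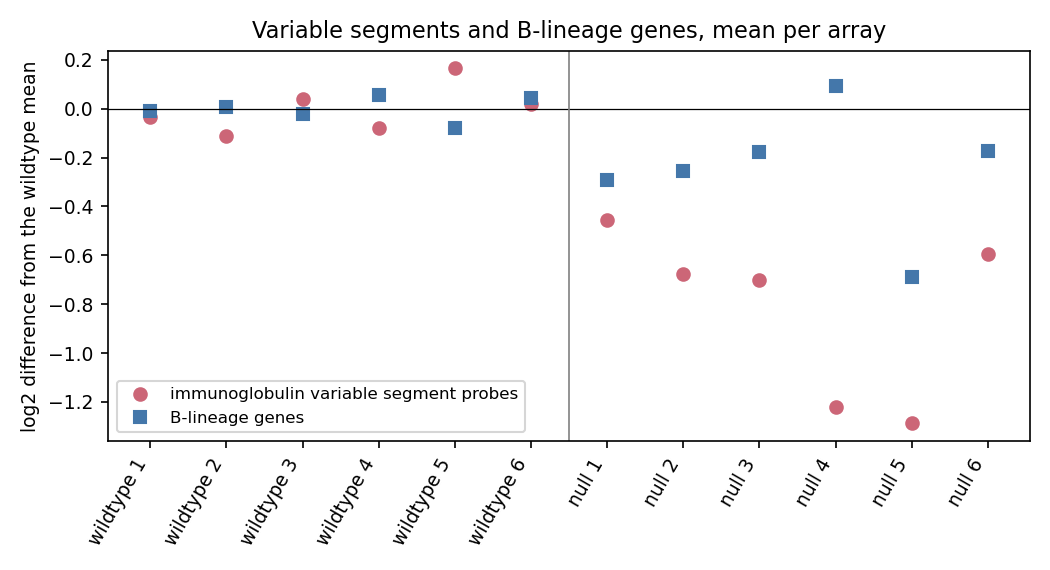
Mean log2 difference from the wildtype mean (vertical axis) on each of the 12 arrays (horizontal axis) for 44 immunoglobulin variable segment probes (circles) and 33 genes of the pre-B receptor and early B-lineage lists (squares). Circles of the null arrays lie between -1.29 and -0.45, and the squares between -0.69 and 0.09.

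The cell cycle and chromatin silencing lists were lower in null cells, by different amounts from array to array. The 35 cell cycle genes had a mean log2 change of -0.21 (camera adjusted p = 2.4e-05; adjusted p = 0.39 with an estimated correlation), led by Nusap1, a spindle protein (-0.48, SE 0.12, limma adjusted p = 0.067). The 28 chromatin silencing factors had a mean of -0.18 (camera adjusted p = 0.00077; adjusted p = 0.38 with an estimated correlation), with the methylation cofactor Uhrf1 at -0.39 (SE 0.13) and the maintenance methyltransferase Dnmt1 at -0.34 (SE 0.12). Of these members 0 passed over all probes (limma; 5 and 8 had an unadjusted p under 0.05), and 1 cell cycle gene and 0 chromatin genes fell when adjusted over the list alone. The 2 list means were -0.32 and -0.25 on BeadChip 1 and -0.10 and -0.11 on BeadChip 2. In null 1 they were -0.09 and 0.01 and in null 2 -0.04 and -0.03, the chromatin values being within the wildtype range of -0.07 to 0.06. In null 5 they were -0.62 and -0.46, and that array also had the highest plasmacytoid dendritic (2.60), T and NK (1.42) and interferon (2.07) means. With null 3 and null 5 left out, chosen after seeing the data, the chromatin list no longer passed (mean -0.09, camera adjusted p = 0.050). Neither list passed with null 3 to 6 left out (cell cycle mean -0.07, adjusted p = 0.051) or with the myeloid and plasmacytoid dendritic means as covariates (-0.06, adjusted p = 0.19), both also chosen after seeing the data.

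The interferon response list and the T and NK, plasmacytoid dendritic, myeloid and plasma cell lists passed as higher in null samples, by amounts that differed between arrays. The 31 interferon response genes had a mean log2 change of 0.85 (camera adjusted p = 2.4e-10; adjusted p = 0.33 with an estimated correlation), and 0 passed singly, over all probes or adjusted over the list alone (limma; 14 had an unadjusted p under 0.05). Their mean stood at 2.07 in null 5, 1.87 in null 6 and 0.96 in null 3 above the wildtype mean, against 0.06 in null 1 and -0.11 in null 2. Ly6a, the stem-cell antigen Sca-1 that interferon induces, was at 2.33 (SE 0.83, limma adjusted p = 0.17), and Irgm1, an interferon-induced GTPase, at 0.40 (SE 0.10, limma adjusted p = 0.073). The 15 T and NK genes had a mean of 0.67 (camera adjusted p = 5.0e-07; adjusted p = 0.19 with an estimated correlation), 8 rising when adjusted over the list alone, among them Thy1, a T-cell surface glycoprotein (1.64, SE 0.40, limma adjusted p = 0.063). Null 1 (0.102) and null 2 (0.163) also lay just above the highest wildtype array (0.0967) on this list. The 7 plasmacytoid dendritic genes had a mean of 0.89 (camera adjusted p = 0.00084; adjusted p = 0.33 with an estimated correlation), 4 rising when adjusted over the list alone, and reached 2.60 in null 5 and 1.26 in null 6. The 19 myeloid genes had a mean of 0.68 (camera adjusted p = 0.00077; adjusted p = 0.41 with an estimated correlation), which was 3.39 in null 3 and at most 0.65 in any other null array. The granule protein Ngp stood at 12.87 in null 3 and between 7.73 and 9.13 in the other null arrays. Without null 3 the myeloid list did not pass (mean 0.14, camera adjusted p = 0.40). The 4 plasma cell genes had a mean of 0.49 (camera adjusted p = 0.0016; adjusted p = 0.19 with an estimated correlation) with 1.32 in null 5, 0.29 in null 1 and 0.19 in null 2, 3 rising when adjusted over the list alone, among them Fkbp11, a folding enzyme of secretory cells (0.78, SE 0.19, limma adjusted p = 0.067). With no filter on dim probes, where all 8 plasma cell genes on the array were tested, the list did not pass (camera adjusted p = 0.056). With the myeloid and plasmacytoid dendritic means as covariates the plasma cell list did not pass (0.21, camera adjusted p = 0.065), and neither did the interferon list (0.14, 0.13).

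**Figure D4:**
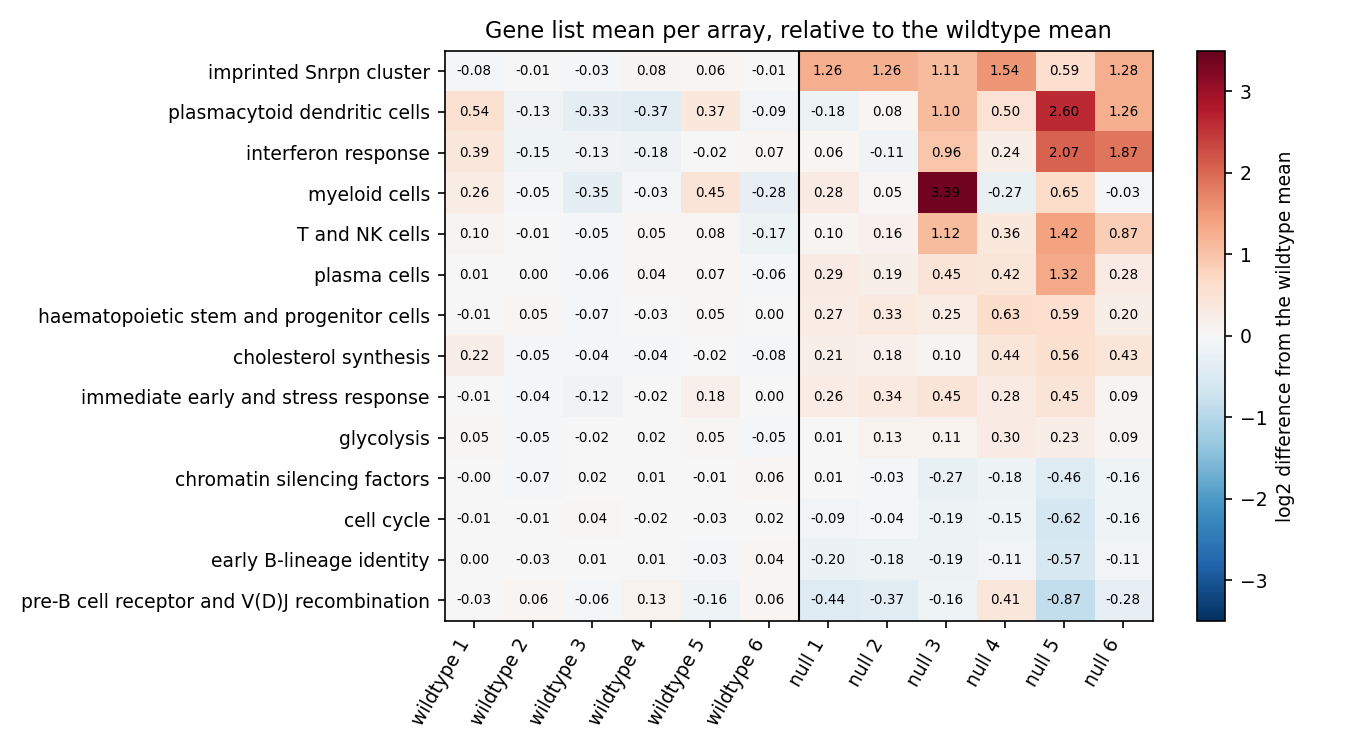
Mean log2 difference from the wildtype mean (colour and printed value) of the 14 gene lists that passed the camera test (vertical axis) on each array (horizontal axis). The myeloid list stands at 3.39 in null 3 and the plasmacytoid dendritic list at 2.60 in null 5, while the Snrpn cluster lies between 0.59 and 1.54 in all 6 null arrays.

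Between BeadChips these lists differed in size: the interferon mean was 1.35 on BeadChip 1 and 0.34 on BeadChip 2, the plasmacytoid dendritic mean 1.43 and 0.36, the myeloid mean 0.16 and 1.19, the T and NK mean 0.87 and 0.47, and the plasma cell mean 0.69 and 0.30. The myeloid list did not pass on BeadChip 1 (camera adjusted p = 0.55), nor did the plasmacytoid dendritic list on BeadChip 2 (0.11). BeadChip 1 held null 4, 5 and 6 and BeadChip 2 held null 1, 2 and 3. A difference between BeadChips therefore cannot be told apart from one between these null arrays. With null 3, 4, 5 and 6 left out, chosen after seeing the data, the interferon (mean -0.02), plasmacytoid dendritic (-0.05), myeloid (0.16) and T and NK (0.13) lists no longer passed. These arrays were left out for high levels of such genes, so the loss was largely fixed in advance. Only null 1 and null 2, both on BeadChip 2, remained. The 9 erythroid genes (camera adjusted p = 0.49) and 6 stroma and endothelium genes (0.32) did not pass, with 0 changed members, and of the 2 tested megakaryocyte genes 0 passed (limma): Cd9 was at 0.41 (SE 0.44), with 8.01 in null 3, and Itgb3 was detected on 0 wildtype and 3 null arrays. Of 5 stem and progenitor genes Lmo2, a haematopoietic LIM-domain factor, rose by 1.03 (SE 0.23) with a call lost in 10 of 12 runs that left out 1 array (limma adjusted p up to 0.11), with 2 passing when adjusted over the list alone; the list was higher (mean 0.38, camera adjusted p = 0.024; adjusted p = 0.19 with an estimated correlation), at 0.48 on BeadChip 1 and 0.27 on BeadChip 2, where it did not pass (camera adjusted p = 0.088). It did not pass without null 5 (0.34, adjusted p = 0.063) or with array weights (0.31, 0.050).

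The cholesterol synthesis, glycolysis and immediate early lists passed the camera test as higher in null cells, and 0 of the 3 did with an estimated correlation. Of 17 cholesterol synthesis genes 3 rose, and 7 when adjusted over the list alone, with a mean of 0.32 (camera adjusted p = 1.9e-05; adjusted p = 0.19 with an estimated correlation) and list means of 0.43 on BeadChip 1 and 0.21 on BeadChip 2. Mvd, which makes isopentenyl diphosphate, rose by 1.25 (SE 0.25), Fdps, which makes farnesyl diphosphate, by 0.67 (SE 0.14) and Sqle, squalene epoxidase, by 0.57 (SE 0.13), with calls lost in 6, 7 and 9 of 12 runs that left out 1 array. Mvd was highest in null 5 (8.26), the array with the highest plasmacytoid dendritic mean. Of 17 glycolysis genes the aldolase Aldoa rose by 0.55 (SE 0.12), with the call lost in 9 of 12 such runs, and was the 1 member that passed when adjusted over the list alone. The glycolysis mean was 0.15 (camera adjusted p = 0.0035; adjusted p = 0.27 with an estimated correlation), at 0.21 on BeadChip 1 and 0.08 on BeadChip 2, where it did not pass (camera adjusted p = 0.088), nor did it with null 3 to 6 left out (0.07, adjusted p = 0.15). Among 23 immediate early and stress genes 2 rose, and 5 when adjusted over the list alone. Of the 2, Fos was at 5.04 ± 0.65 in wildtype and 7.18 ± 1.10 in null cells, with its call lost in 9 of 12 such runs. It was undetected on 4 wildtype arrays, so its change has no exact size. Its partner Jun was detected on 1 wildtype array and was at least 1.40-fold higher. The list had a mean of 0.31 (camera adjusted p = 0.00077; adjusted p = 0.19 with an estimated correlation), at 0.33 and 0.29 on BeadChips 1 and 2. The 22 genes of the p53 response went both ways and did not pass as a list (camera adjusted p = 0.14). Trp53inp1, a p53-induced autophagy protein, fell by 0.70 (SE 0.14) and Rrm2b, a p53-induced ribonucleotide reductase subunit, fell by 0.48 (SE 0.10), with calls lost in 5 and 9 of 12 such runs, while Cdkn1a, the p21 inhibitor, was at 1.09 (SE 0.29, limma adjusted p = 0.080); 7 were higher and 3 lower when adjusted over the list alone. The 21 Bcl2 family and apoptosis genes (camera adjusted p = 0.14) and the 33 Myc targets (0.31) had 0 changed members.

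On chromosome 17 the 8 tested genes of the list fixed as neighbours of Smchd1 had 0 changed members (camera adjusted p = 0.64). That list does not cover both sides evenly. Counted in tested genes from Smchd1, it ran from -6 (Dlgap1) to 1 (Ndc80), and its last member, Mettl4, lay at 61. Lbh, which changed, lay at 5, outside the list. In a wider window, chosen after its values were seen, 5 of the 50 tested genes nearest in order on chromosome 17 changed, against 137 of 9763 other placed genes (odds ratio 7.80, two-sided Fisher exact p = 0.00074). Chromosome 17 as a whole had 9 changed among 520 (two-sided Fisher exact p = 0.57). Nlrc4, C030034I22Rik, Yipf4 and 1 of 4 Spast probes fell, and 1 of 2 probes of Lbh, a transcriptional cofactor, rose by 1.39 (SE 0.09). The other Lbh probe was at 0.24 (SE 0.07, limma adjusted p = 0.12). C030034I22Rik was at least 5.26-fold lower on 1 of its 2 probes and Yipf4, a Golgi membrane protein, was detected on 0 null arrays and was at least 1.38-fold lower.

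**Figure D5:**
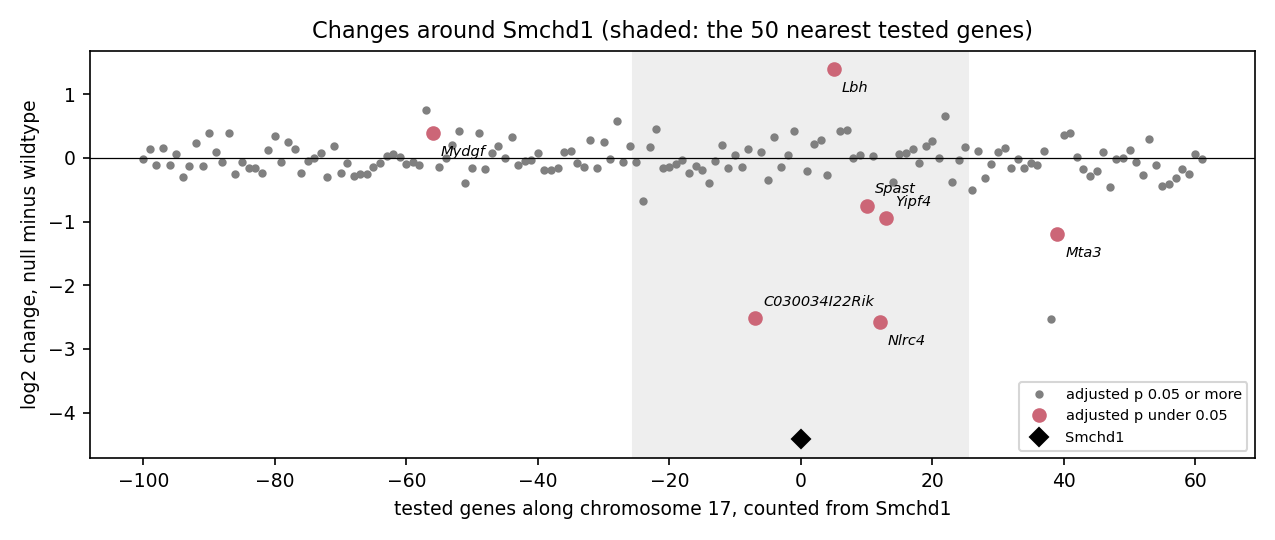
Log2 change, null minus wildtype (vertical axis), of tested genes on the part of chromosome 17 around Smchd1, in their order from it (horizontal axis), each gene at its probe of smallest p; larger points passed the limma test. The shaded 50 nearest genes hold 5 that passed, of which Lbh at 1.39 is the 1 that rose.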

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

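The tests of the cell-type explanations in this part were chosen after the values were seen. In each group of 6 arrays the highest or lowest array was set against the rest by Dixon's ratio at its 95% critical value, for 300 groups of single probes and 58 groups of list means. It singled out 40 probe values and 10 list means, where chance singles out about 1 in 20 groups. Values are log2 levels, with the other arrays of the same group in parentheses where given.

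Null 3 stood above the other null arrays for Ngp at 12.87 (7.73 to 9.13), Cd9 at 8.01 (4.87 to 5.36) and Vcam1 at 7.45 (4.54 to 5.30). It also did for the means of the myeloid list at 10.88 (7.23 to 8.14), the erythroid list at 7.51 and the megakaryocyte list at 6.37.

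Null 5 stood below the other null arrays for Ndn at 7.74 (8.85 to 9.36), Isl1 at 6.03, Tnfrsf19 at 6.05, Myb at 5.67, Irf4 at 8.58, Cdc6 at 8.61 and Plk1 at 10.95. It stood above them for H13 at 10.78, Fkbp11 at 10.16, Xbp1 at 11.89, Bad at 9.54 and Mvd at 8.26. Of its list means, early B-lineage at 7.90, cell cycle at 9.53 and Y-linked genes at 7.24 were low and plasma cells at 10.51 was high.

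Null 4 stood above the other null arrays for Igf2 at 14.15 (4.75 to 5.91), H19 at 14.05 (4.50 to 5.56), Car2 at 9.58, Egfl7 at 9.72, Wdr43 at 10.68, Srm at 12.09, Cdkn1a at 9.46, Ccng1 at 10.87, Cdkn2a at 9.42, Pfkl at 10.77 and Eno1 at 12.66. It stood below them for Trp53inp1 at 9.30, and its mean of the other imprinted genes was high at 7.95.

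Among wildtype arrays, wildtype 1 was low for Nlrc4 at 6.47 and C030034I22Rik at 4.79, and high for Uhrf1 at 13.03, Tuba3a at 6.66, Srebf2 at 8.12 and the cholesterol synthesis mean at 7.18. Wildtype 5 was high for Fos at 6.32, Junb at 7.54, Fosb at 5.11, Ccnd1 at 10.19 and the mean of the Smchd1 neighbours at 7.36. Wildtype 4 was high for Lmo4 at 7.89 and low for Kdm5d at 5.95, and wildtype 3 was high for Pcdhgb4 at 5.61 and Spib at 10.30.

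Markers of other blood cells were higher in some null arrays, although the cells had been sorted. A lower share of pre-B cells alone would raise all other types alike. The myeloid mean minus the plasmacytoid dendritic mean was -1.96 in null 5 (SE 0.50) and 2.29 in null 3 (SE 0.42). These arrays were picked for the highest mean of either list, which favours opposite signs. The SEs take genes as independent, against estimated correlations of 0.77 (myeloid) and 0.79 (plasmacytoid dendritic). The lists rose unequally in these arrays, but the test cannot decide on that explanation. Granulocyte-lineage RNA may be present in null 3, where 17 of the 19 tested myeloid genes were highest among the 12 arrays. Whether other cells account for many of the 215 changed probes cannot be told apart from genotype: 93.5% lay outside the wildtype range in both null 1 and null 2, but calling on these same arrays fixes most of that share (84.2% have all 6 null arrays beyond all wildtype arrays), and both arrays exceeded every wildtype array on 3 lists of other cells (T and NK, plasma, stem and progenitor). The changed probes numbered 176 without null 3 and 5, 159 without null 3 to 6 and 85 with the myeloid and plasmacytoid dendritic means as covariates. With these covariates all 215 kept their direction at a median of 87.5% of the log2 change (quartiles 73.8% and 97.7%). The 215 were called on these same arrays, which largely fixes their direction. The T and NK, plasma and progenitor lists were not among the covariates. Neither the lower count nor the kept direction therefore decides on other cells. A response of the null cells or animals to interferon, which the design does not separate from genotype, stays open and was not tested.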

How the results depend on the processing

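Arrays with null 3 and 5, or 3 to 6, left out and the list means as covariates were chosen after seeing the data. With null 3 to 6 left out, the remaining null 1 and null 2 both lie on BeadChip 2, while wildtype arrays come from both. Among the 44 probes called for named genes, 1029 of 1307 comparisons kept their call, 278 lost it and 0 reversed. Only 6 of the 44 probes kept their call in every setting, and some settings, such as the authors' values, could hardly change a call. Against 215, the number of changed probes was 92 with median scaling, 101 with no filter, 12 and 43 within BeadChips 1 and 2 (fewer samples), 104 with the replicate number as a block, 380 with array weights, 85 with covariates, and 68 to 319 leaving out single arrays. No pairing by replicate number was seen in the levels (correlations -0.29 to 0.085). These cannot decide whether samples were paired, since 0 of the 6 pairs of equal number shared a BeadChip and the labels name no pairs. Against 14, the lists past the threshold were 8 with null 3 to 6 left out, 7 with covariates and 0 with an estimated correlation. The covariate fit gives no value for the myeloid and plasmacytoid dendritic lists themselves. Sex was not run as a covariate, as Y-linked genes were detected on all 12 arrays and Xist on 0. Signal over background of 3.08 to 4.43 limits dim probes.

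The following reversed, and the cause was not tested; for a gene the sign of its change, and for a list camera's direction against all other genes, which can turn while the mean keeps its sign. With median scaling the Myc targets mean was -0.061. With no filter the germline direction turned when all 25 genes on the array were tested, while the mean of the 3 genes tested in the main fit stayed at -0.057. On BeadChip 1 Pcdhb4 was at -0.047, Snurf 0.15, Hoxa7 -0.028, Ngp -0.077, Cd9 -0.054, Ddx3y 0.014 and the erythroid mean -0.022. On BeadChip 2 Spast probes were at 0.050 and 0.034 and the germline mean 0.068. With array weights Kdm5d was at 0.0067 and Spast 0.062. Without null 3 and 5 Cd9 was at -0.16, Kdm5d 0.0028, Kdm5c 0.081, Spast 0.15, and the later B-cell, myeloid and erythroid means -0.0075, 0.0082 and -0.30. With null 3 to 6 left out Pcdhgb4 was at -0.12, Serpina3g -0.052, Icam4 -0.049, Car2 -0.083, Cd9 -0.18, Mecom 0.054, Cd7 -0.16, Ly6a -0.021, Bid -0.00081, Eif2s3y 0.031, Spast 0.20 and 0.19, and the germline, erythroid, plasmacytoid dendritic, interferon and Bcl2 family means 0.16, -0.44, -0.050, -0.024 and -0.050. With covariates Pcdhb4 was at -0.011, Icam4 -0.039, Cd9 -0.10, Eif2s3y 0.015, Kdm5c 0.051, Spast 0.21 and 0.062, and the later B-cell, erythroid and Bcl2 family means -0.084, -0.25 and 0.053. Leaving out single arrays gave Pcdhb4 -0.039 to 0.069, Cd9 -0.082 to 0.55, Ddx3y -0.11 to 0.0050, Kdm5c -0.16 to 0.012, Spast -0.080 to 0.092, and the later B-cell and erythroid means -0.013 to 0.15 and -0.29 to 0.14.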

Other observations

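All tests in this part were chosen after the result was seen, except both counts over other splits of the arrays and the test of fewer clones. The segment group used in that last test was chosen after its values were seen. Ccnd1, which encodes cyclin D1 and was chosen after its values were seen, rose on all 3 of its tested probes, by 1.30 (SE 0.19), 1.27 (SE 0.15) and 1.18 (SE 0.12) on the log2 scale (limma adjusted p = 0.0038, 0.00057 and 0.00029). The imprinted neighbours Igf2, a fetal growth factor, and H19, its untranslated partner, were both chosen after their values were seen. They stood at 14.15 and 14.05 in null 4 alone, and the comparison of null with wildtype did not pass for either (limma adjusted p = 0.47 and 0.49). The labels do not say whether the null 4 sample differed in origin or sorting, so what its values stand for is uncertain.

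Chance in the grouping of arrays is argued against for the count of changed probes: of 100 splits drawn from 462, only 1, the real one, gave 215, and the highest other gave 1. With 100 splits drawn, the real one included, the share could not have been under 1 of 100. For the gene lists 1 of 100 splits reached the real 14, but the highest other gave 13 and the median other 6, so other splits also call many lists. Other splits can keep part of the contrast of null with wildtype, which was not separated from another structure of the arrays.

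Called genes lay close to Smchd1 in gene order, although chromosome 17 as a whole held 9 among 520 tested genes (two-sided Fisher exact p = 0.57). The 8 tested genes listed beforehand as neighbours, which lay mostly on 1 side of Smchd1, held 0. Chance placement is argued against: over all window sizes from 10 to 161 genes, the best window was as dense in called genes for 10 of 9814 centres, Smchd1 included (one-sided exact rank p over centres = 0.00102). Base differences under the probes in a linked segment would lower a signal, which the 1 called gene that rose, Lbh, does not show. The probes of Lbh disagree as well, at 1.39 and 0.24 (limma adjusted p = 0.12 for the latter), and a probe effect on Lbh was not tested. For the genes that fell base differences may apply, since of C030034I22Rik and Spast, the 2 with further probes, 0 had all of them lower. Cox7a2l, 38 genes from Smchd1, is a possible example: the lowest null array differed from the wildtype mean by -5.92 log2 on 1 of its probes. That probe stood at 6.03 in null 1 and 6.09 in null 2, at 10.90 to 11.29 in the other null arrays and at 11.95 ± 0.08 in wildtype. The other Cox7a2l probe was at -0.22 (SE 0.09). The allele alone, which every null array carries, does not give such a gap between null arrays. For these 5 genes a linked segment of another strain or a local effect of the trapped allele cannot be told apart from an effect of losing the protein, because every null array carries the allele. Nor can they be for the lower level of Mta3 beside Cox7a2l, which was also lowest in null 1 and null 2.

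Immunoglobulin variable segment probes were lower in null arrays. Segments fell short of the B-lineage genes by -0.57 on the log2 scale (two-sided exact permutation p = 0.0022, the smallest that 6 against 6 arrays can give). The segment group was chosen for its lower values, so this p-value cannot decide whether a lower share of B-lineage cells is the whole cause. How far other cells express the B-lineage list genes was not tested. Whether a repertoire of fewer clones contributes cannot be decided from the spread over segments of an array's deviations from the wildtype mean. That spread was 0.65 ± 0.21 in null and 0.35 ± 0.08 in wildtype arrays (two-sided exact permutation p = 0.0087). The wildtype arrays themselves set the mean, which narrows their spread and favours a wider one in null arrays. Unequal falls of segments in all clones would widen that spread as well, and cross-hybridisation between similar segments of a family was not tested.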
